A study of Homo sapiens with 42 samples.

How the data were processed

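Gene expression was measured by RNA-seq in 25 libraries of H1 human embryonic stem cells, and BCOR binding by ChIP-seq in 4 conditions with 1 ChIP library each. Per the labels, cells grew in mTeSR on Matrigel, RNA was taken with an RNeasy Micro kit, and libraries were made with TruSeq reagents. Expression values are FPKM (fragments scaled by gene length and library size), named normalized FPKM by the authors, for 58243 genes. The tools given in the submitters' processing notes are Trimmomatic 0.32, STAR 2.4.2a, SAMtools 1.0, Salmon 0.8.2, DESeq2 1.16.1 and MACS2 2.1.0.20150731, with GRCh38/hg38 as the build. Which of them made the FPKM values, the annotation, the filters and the scaling between libraries are not given in the sources used here. The FPKM values of a library sum to between 1058716 and 3192421, so the scaling did not set equal sums. The number of reads behind each value is not in the table, and depth is therefore unknown.

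The peak lists are in the broadPeak format. The deposited lists give for each peak a score, which was checked to be 10 times the −log10 q-value in whole numbers. They also hold, as the deposited values from the peak caller, the fold enrichment of the peak over background as a ratio, the −log10 p-value and the −log10 q-value. Thresholds and controls used in peak calling are not given in the sources used here. The labels of the wild-type ChIP sample conflict, since its title names wild type and its description names the knockout list; lists were assigned by title. The labels also give different BCOR antibodies for wild type and for the other 3 conditions, and a fixation with EGS and formaldehyde in RNF2R cells but formaldehyde alone in wild-type and knockout cells. ChIP samples labelled for other proteins and histone marks were not analysed here.

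Samples were grouped from the labels alone. The groups are shBCOR, shCntrl1, shRAB (shRNAs against RING1 and RNF2) and shCntrl2 with 2 libraries each, wild type with 1 library, KDM2B knockout with 2 libraries from clones 1 and 2, and the lines RNF2R and BCORR with 1 library on each of days 0 to 6. Comparisons were shBCOR against shCntrl1, shRAB against shCntrl2, KDM2B knockout against wild type, shCntrl2 against shCntrl1, the shBCOR effect minus the shRAB effect, the slope over days in each line, and the BCORR slope minus the RNF2R slope. The groups, comparisons, gene lists, rule for named genes and most alternatives were fixed before the data were examined. The labels of the shRNA libraries do not say whether the replicates were separate cultures, so p-values there measure only the spread between these samples. Each time-course line is a single series with 1 library per day. The p-values of slopes and of their difference thus measure scatter around straight lines, not spread between cultures.

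FPKM values were transformed to log2(FPKM + 0.5). Genes with FPKM of at least 0.5 in at least 2 libraries of a fit were tested, which left 27782 genes among the 11 libraries without a time course and 27166 genes among the 14 time-course libraries. The pseudocount lowers fold changes of genes near 0. Models were fitted with limma 3.58.1 in R 4.3.3, with a mean-dependent empirical Bayes prior. The group model gave 1 mean per group. The trend model gave each line its own intercept and slope per day. All limma tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the genes tested, and an adjusted p under 0.05 counted as passing. Standard errors (SE) come from the limma fit. Adjusted p-values printed with genes are from limma unless another test is named. The fits assume that the lone wild-type library varies like the other groups.

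Genes were named by a rule. It takes the targeted genes BCOR, RNF2, RING1 and KDM2B, up to 10 genes with the largest rise and up to 10 with the largest fall among those that passed, with FPKM of at least 1 on the higher side, a gene symbol and no overlap between groups, and up to 4 members of each gene list. Pseudogenes and small RNA genes that this rule also took are given only as counts or left out. Gene symbols came from the table, and 40188 genes were matched by symbol to RefSeq, of which 19118 were protein-coding. All coordinates are GRCh38.

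The 22 gene lists were PRC1.1 subunits, other PRC1 subunits, PRC2 subunits, primed pluripotency, naive pluripotency, primitive streak and mesendoderm, endoderm, mesoderm and heart, neural ectoderm, neural crest and placode, trophectoderm and amnion, HOX clusters, germline, cell cycle inhibitors, p53 targets, cell cycle genes, interferon response, fibroblast, stress and immediate early, mitochondrial transcripts, blood and endothelium, and TGF-beta, BMP and WNT signalling. Of 409 listed genes, 408 were found. Each list was tested with camera from limma, with a preset correlation of 0.01, and p-values were adjusted over the lists of a comparison; the correlation was estimated from the residuals as an alternative. Counts of members that passed are given over all genes tested and adjusted over the list alone. A rotation test (fry) was run beside camera and is not used here.

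Peaks were compared with interval overlap of at least 1 bp in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. Chance overlap was the mean of 20 shuffles of the peaks within their chromosomes. Shares have Wilson 95% intervals, which cover counting error only. The build was checked by the share of RefSeq gene ends with a wild-type peak within 1 kb, which was 32.4% in place and 4.55% after a shift by 100 kb. A protein-coding gene was called BCOR-bound when a wild-type peak lay within 1 kb of either end, since the reference gives no strand and start sites could not be told from end sites. Calls among bound and unbound genes were compared with two-sided Fisher's exact tests, adjusted over 10 tests. Fold changes and slopes of different comparisons were compared by Spearman correlations across genes, which are not independent replicates.

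Alternatives covered pseudocounts of 0.1 and 1, no filter and a minimum of 2 FPKM, scaling to equal sums of FPKM or by median of ratios, robust empirical Bayes, fits on the compared groups alone, the replicate number as a block, each library left out in turn, other control groups, days 1 to 6 alone, a rank trend, peak thresholds, overlaps and distances. A fit on protein-coding genes alone and the gene body as the bound region were added after seeing the data. The replicate numbers do not pair the shRNA samples by any label, and replicate differences correlated between −0.076 and 0.042 across genes, so the block is an alternative. The pipeline was tested on simulated data. With known changes added to 200 genes, 64% of 4-fold and 11% of 2-fold changes were recovered between groups of 2 libraries, and 39.5% and 0% against the lone wild-type library. For the RNF2R trend, 64.5% of 4-fold and 19.5% of 2-fold changes over 6 days were recovered. In the real data 2871 genes passed in shBCOR, 6772 in the knockout and 5992 in the RNF2R trend. The adjusted threshold is stricter when only 200 genes change, so these rates do not give the recovery in the real comparisons.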

Results

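RNA-seq was done on 25 libraries of H1, a line of human embryonic stem cells, and BCOR ChIP-seq on 4 conditions of the same line. BCOR is a subunit of PRC1.1, a non-canonical form of the Polycomb repressive complex PRC1 that also holds KDM2B, PCGF1, RYBP or YAF2 and the ubiquitin ligases RING1 and RNF2. The series asks which genes this complex represses. The libraries labelled shBCOR (shRNA against BCOR), shRAB (shRNAs against RING1 and RNF2), shCntrl1 and shCntrl2 (control shRNAs) number 2 each. There was 1 wild-type library, and the KDM2B knockout had 2 libraries, from clones 1 and 2. The lines RNF2-R and BCOR-R, written RNF2R and BCORR here, were followed on days 0 to 6 with 1 library per day. Doxycycline (dox) was present at 1 µg/ml at day 0 and at no later day; how these lines were made is not given in the sources used here. FPKM values summed to between 1058716 (RNF2R day 6) and 3192421 (shCntrl1 replicate 1), and between 19692 and 23613 genes reached an FPKM of 0.5. Transcripts of the mitochondrial genome took between 10.4% (shCntrl1 replicate 2) and 22.4% (RNF2R day 0) of the sum. Values after ± are the SE of the limma fit unless marked SD.

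BCOR mRNA (ENSG00000183337, chromosome X, 40051246 to 40177277) stood at 22.9 and 15.5 FPKM in the libraries labelled shBCOR and at 20.0 and 21.3 in shCntrl1, a log2 difference of −0.13 ± 0.17 that did not pass (adjusted p = 0.73). BCOR was at 28.9 and 29.9 FPKM in shCntrl2, 17.7 and 18.4 in shRAB, 55.2 in wild type, and 86.9 and 95.8 in the KDM2B knockout. RNF2 (ENSG00000121481, chromosome 1, 185045558 to 185102603) fell in shRAB, from 33.9 and 30.6 FPKM in shCntrl2 to 16.2 and 16.3, a log2 change of −0.97 ± 0.11 (n = 2 and 2, limma adjusted p = 0.01; adjusted p rose past 0.05 when libraries were scaled to equal sums, at −0.86). RING1 (ENSG00000204227, chromosome 6, 33208500 to 33212716) was at 7.37 and 8.05 FPKM in shRAB and 11.1 and 15.4 in shCntrl2 (log2 −0.73 ± 0.19, adjusted p = 0.17). KDM2B (ENSG00000089094, chromosome 12, 121408461 to 121582279) fell from 118 FPKM in wild type to 27.3 and 30.2 in the knockout, by 2.01 ± 0.22 on the log2 scale (adjusted p = 0.0026). In the RNF2R line, RNF2 dropped between days 0 and 1, from 28.8 to 3.98 FPKM, and then lay between 2.54 and 4.64. In the BCORR line, BCOR stood at 46.4 FPKM on day 0, 11.6 on day 1 and between 14.8 and 23.2 on days 2 to 6. Neither of these slopes over all days passed (RNF2 −0.27 ± 0.13 per day, adjusted p = 0.16; BCOR −0.03 ± 0.09, adjusted p = 0.91).

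The comparison of shBCOR with shCntrl1 asks which genes BCOR holds down in these cells. Because BCOR mRNA was not called lower in them, the group is called the libraries labelled shBCOR. Single genes of the primitive streak and early endoderm, given here, were far higher in these libraries; their lists had an adjusted p = 0.056 each with an estimated correlation. EOMES, a T-box factor (ENSG00000163508, chromosome 3, 27715953 to 27722713), rose from 0.434 ± 0.167 FPKM to 95.5 ± 1.30 (SD, n = 2 and 2), a log2 change of 6.70 ± 0.27 (adjusted p = 0.00011). MIXL1 (chromosome 1, 226223664 to 226227060), a homeobox factor of the streak, rose by 6.10 ± 0.17 (adjusted p = 6.8e-05), and CER1 (chromosome 9, 14717326 to 14722733), a secreted NODAL antagonist, by 6.02 ± 0.19 (adjusted p = 8.6e-05). Among the largest falls were the forebrain factors LHX5 (−4.36 ± 0.86, adjusted p = 0.024) and FEZF1 (−3.89 ± 0.30, adjusted p = 0.00069) and the neural factor SOX21 (−3.73 ± 0.26, adjusted p = 0.00053). The neural ectoderm list as a whole did not pass, with 2 of 18 higher, 1 lower and a median of −0.06 (camera adjusted p = 0.55).

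By gene group, 11 of 15 measured primitive streak and mesendoderm genes rose in the libraries labelled shBCOR and none fell (12 adjusted over the list alone; median log2 3.50; camera adjusted p = 4.2e-16, adjusted p = 0.056 with an estimated correlation). FGF17 (5.99 ± 0.28), WNT3 (3.50) and MIXL1 were among them. In the endoderm list 12 of 16 rose, also 12 adjusted over the list alone (median 3.08; camera adjusted p = 1e-13, adjusted p = 0.056 with an estimated correlation), among them SOX17 (5.46 ± 0.29), GATA6 (5.15 ± 0.25), GATA4 (5.04 ± 0.15) and the chemokine receptor CXCR4 (4.90 ± 0.23). In the mesoderm and heart list 10 of 19 rose (13 adjusted over the list alone; camera adjusted p = 3.7e-10, adjusted p = 0.056 with an estimated correlation), with FOXC1 at 2.81. The fibroblast list had 5 of 13 higher, 7 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00084, adjusted p = 0.056 with an estimated correlation), with COL5A1 at 2.53 and VIM at 1.34. TGF-beta, BMP and WNT signalling had 6 of 20 higher and 2 lower, also 6 and 2 adjusted over the list alone (camera adjusted p = 0.013, adjusted p = 0.38 with an estimated correlation), with the WNT inhibitor DKK1 at 3.11 and the feedback inhibitor SMAD6 at 2.09. The p53 targets had 4 of 18 higher and 1 lower, 6 and 1 adjusted over the list alone (camera adjusted p = 0.013, adjusted p = 0.44 with an estimated correlation), with GDF15 at 1.95 and CCNG1 at −0.41. The call of CCNG1 ended with equal sums. Mitochondrial transcripts shifted down as a list (camera adjusted p = 0.0023, adjusted p = 0.38 with an estimated correlation) with 0 of 15 past the threshold in limma and 5 lower at an unadjusted p under 0.05. MT-ND1 was at −0.37 ± 0.10 (adjusted p = 0.06). Their share of the FPKM sum was 12.88% and 14.15% in the libraries labelled shBCOR, between the 15.57% and 10.39% of the shCntrl1 replicates.

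The primed pluripotency list went both ways in the libraries labelled shBCOR. Of 27 genes, 6 rose and 7 fell (7 and 9 adjusted over the list alone; camera adjusted p = 0.72; median −0.20 and mean 0.21). The pluripotency factor SOX2 fell by 1.66 ± 0.13, and the DNA methyltransferase DNMT3B fell by 0.92 ± 0.08, from 277 to 147 FPKM, while GDF3 (3.56) and NODAL (3.54), ligands of the NODAL pathway, rose. PRC1.1 subunits had 1 of 10 higher (YAF2, 2.86, adjusted p = 0.016; camera adjusted p = 0.43), other PRC1 subunits 1 of 20 lower (AUTS2, −1.84; camera adjusted p = 0.72), and PRC2 subunits 1 of 11 higher (PHF19, 0.74) and 1 lower (EZH1, −0.97; camera adjusted p = 0.19). The calls of AUTS2 and EZH1 ended with equal sums. Naive pluripotency had 1 of 11 higher, TBX3 at 4.11, and 1 lower, ALPPL2 at −1.16 (camera adjusted p = 0.89). The cell cycle inhibitor CDKN2A (chromosome 9, 21967752 to 21995324), which encodes p16INK4a and p14ARF, rose by 2.19 ± 0.21 (adjusted p = 0.0015). Germline genes had 1 of 13 higher and 2 lower (camera adjusted p = 0.13), and interferon response 3 of 10 higher and 1 lower (camera adjusted p = 0.85). In all, 2871 of 27782 genes passed, 1718 higher and 1153 lower (59.8% higher, and 72.8% with equal sums). The count was 1150 without shBCOR replicate 1, 1155 without replicate 2, 1358 in a fit of these groups alone and 1872 with the replicate block. Against shCntrl2 it was 5631 and against both controls 4558.

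In shRAB, streak genes also rose and 7 of 10 measured HOX genes rose with them. EOMES rose from 0.121 to 12.0 FPKM, by 4.33 ± 0.27 on the log2 scale, CER1 by 4.30 ± 0.19 and MIXL1 by 3.98 ± 0.17 (n = 2 and 2, adjusted p = 0.00054, 0.00011 and 0.0001). The cystatin gene CST1 (chromosome 20, 23747562 to 23750935) had the largest rise, 5.37 ± 0.36 (adjusted p = 0.00087). HOXD13 (chromosome 2, 176087487 to 176095944) rose by 1.76 ± 0.17, HOXA7 by 1.65 ± 0.18 and HOXD10 by 1.56 ± 0.21; HOXD11 also passed and was listed at 0 in shCntrl2. Among the falls were HHIP, a hedgehog-binding protein (−1.97 ± 0.16), and IDO1, an enzyme of tryptophan breakdown, from 111 to 46.3 FPKM (−1.25 ± 0.14).

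By list, 10 of 15 streak and mesendoderm genes rose in shRAB and none fell (13 adjusted over the list alone; median 2.39; camera adjusted p = 6.4e-26, adjusted p = 0.033 with an estimated correlation). All 10 measured HOX genes passed when adjusted over the list alone, with a median of 1.60 (camera adjusted p = 1.1e-15, adjusted p = 0.033 with an estimated correlation). The others of 39 HOX genes with coordinates did not pass the filter on FPKM in the group fit. That filter asks for 2 libraries of any group, so the shRAB libraries alone could admit a gene near 0 in shCntrl2. HOXD11, at 0 in shCntrl2, had a log2 change of 1.29. Such a filter favours rises, so these HOX values hold for the measured genes and not for the clusters as a whole. Endoderm had 5 of 16 higher, 8 higher and 1 lower adjusted over the list alone (camera adjusted p = 4.1e-07, adjusted p = 0.16 with an estimated correlation), with SOX17 at 3.24 and FOXA2 at 2.35. Mesoderm and heart had 3 of 19 higher, 7 adjusted over the list alone (camera adjusted p = 2.2e-06, adjusted p = 0.068 with an estimated correlation). TGF-beta, BMP and WNT signalling had 3 of 20 higher, 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0053, adjusted p = 0.2 with an estimated correlation), with SMAD7 at 1.91. The fibroblast list had 1 of 13 higher, PDGFRB at 0.98, and 3 adjusted over the list alone (camera adjusted p = 0.021, adjusted p = 0.17 with an estimated correlation). Primed pluripotency had 5 of 27 lower, among them DNMT3B (−0.71), PRDM14 (−0.68) and LIN28A (−0.60), and 1 higher, NODAL (2.55); 9 lower and 4 higher passed adjusted over the list alone. Its camera adjusted p of 0.034 became adjusted p = 0.2 with an estimated correlation and 0.18 with the replicate block. With equal sums it was 0.37, with 2 genes higher and 0 lower, so that the calls of DNMT3B, PRDM14 and LIN28A ended. Stress and immediate early genes shifted down (EGR1 −1.65; 1 of 18 lower, 2 adjusted over the list alone; camera adjusted p = 0.0037, adjusted p = 0.2 with an estimated correlation). So did cell cycle genes (0 of 22 past the threshold in limma, 5 lower at an unadjusted p under 0.05; camera adjusted p = 0.006, adjusted p = 0.2 with an estimated correlation and 0.078 with equal sums). Mitochondrial transcripts shifted down as well (0 of 15 in limma, 3 lower at an unadjusted p under 0.05; camera adjusted p = 0.00012, adjusted p = 0.2 with an estimated correlation). Their share of the FPKM sum overlapped between the groups, at 12.98% and 13.25% in shRAB and 13.59% and 13.12% in shCntrl2. CDKN2A rose by 2.43 ± 0.21 (adjusted p = 0.0027). In all, 385 genes passed in shRAB, 306 higher and 79 lower. The count was 177 without shRAB replicate 1, 174 without replicate 2, 256 in a fit of these groups alone, 244 with the replicate block, 4039 against shCntrl1 and 1645 against both controls.

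**Figure D1:**
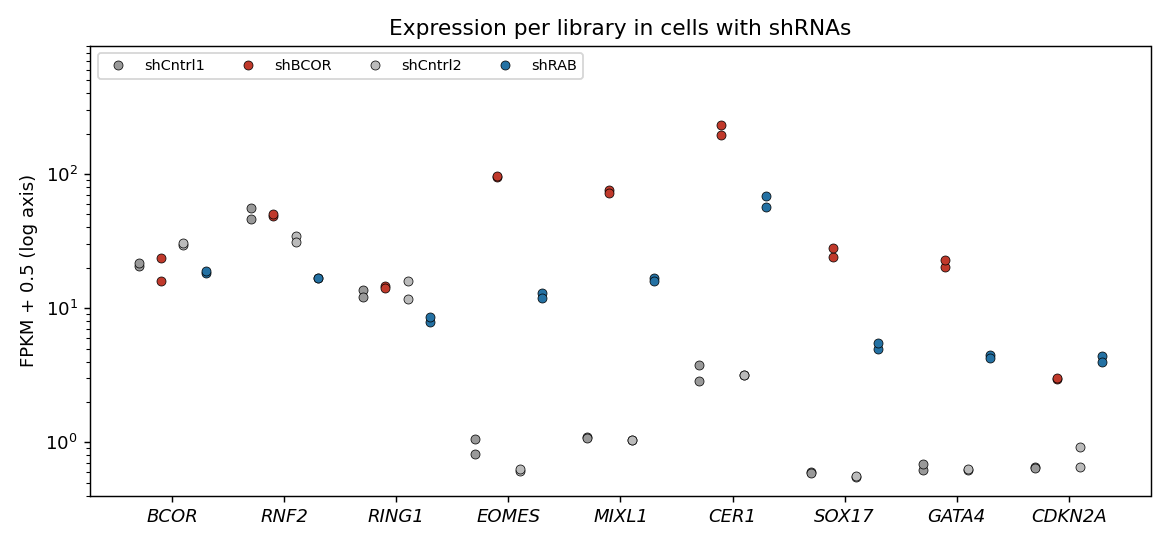
FPKM + 0.5 on a log axis in each of the 8 shRNA libraries (1 point per library) for the targeted genes and 6 genes that rose. EOMES lay at 95.5 FPKM on average in shBCOR and 12.0 in shRAB, while BCOR in shBCOR overlapped with shCntrl1.

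Most measured streak and mesendoderm genes rose in both shRNA comparisons, which had no libraries in common. With an estimated correlation the list passed in shRAB but not in the libraries labelled shBCOR. The overlaps given next cover all genes. Of 1718 genes higher in the libraries labelled shBCOR and 306 higher in shRAB, 216 were the same, against 18.9 expected if calls were independent, and 35 were lower in both against 3.3 expected; 8 went opposite ways. Changes correlated across genes, which are not independent replicates, at Spearman 0.29 and Pearson 0.24; 10 such pairs of comparisons were computed. Overlap of higher genes with the BCORR trend was 335 against 53 expected for shBCOR (Spearman 0.26) and 70 against 8.8 for shRAB (Spearman 0.23). The KDM2B knockout shared 456 higher genes with shBCOR against 231.0 expected, but 512 genes went opposite ways (Spearman 0.01). The group comparisons come from the same fit and share the same spread per gene, so their calls are not independent. No expected number was worked out for opposite calls, so an excess of shared calls alone does not show agreement.

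The control shRNA groups, which have the same genotype label, also differed. Between shCntrl2 and shCntrl1, 1705 genes passed, 680 higher and 1025 lower (39.9% higher), and with equal sums 1007 passed, of which 74.5% were higher. RNF2 was lower in shCntrl2 by −0.62 ± 0.11 (adjusted p = 0.032), and BCOR stood 0.50 higher (adjusted p = 0.13); the call of RNF2 ended with equal sums. Of the 22 lists, mitochondrial transcripts passed, with 5 of 15 lower and 12 lower adjusted over the list alone (median −0.56; camera adjusted p = 3e-07, adjusted p = 0.51 with an estimated correlation). Mitochondrial transcripts took 15.57% and 10.39% of the FPKM sum in shCntrl1 replicates 1 and 2, and 13.59% and 13.12% in shCntrl2. The shares in shCntrl2 thus lay between those of the shCntrl1 replicates. Without shCntrl1 replicate 1 the count of genes that passed was 2257, with 1369 higher and 888 lower, so that the balance turned. It was 363 without shCntrl1 replicate 2, 413 without shCntrl2 replicate 2, 250 in a fit of these groups alone and 192 with the replicate block.

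The KDM2B knockout asks what the loss of KDM2B, the subunit that brings PRC1.1 to unmethylated CpG islands, does to expression. Among the genes that rose in the knockout clones were those of a collagen, a stress cytokine and a pair of cell cycle inhibitors. COL3A1, a fibrillar collagen (chromosome 2, 188974373 to 189012746), rose from 0.0710 FPKM to 46.7 ± 22.1 (SD, n = 2 clones; log2 6.28 ± 0.38, adjusted p = 0.00053). GDF15, a stress cytokine and p53 target (chromosome 19, 18386158 to 18389176), rose by 5.66 ± 0.44 (adjusted p = 0.001), and ZIC1, a neural zinc finger factor (chromosome 3, 147409365 to 147416719), by 5.36 ± 0.35 (adjusted p = 0.00067). CDKN2A rose by 4.17 ± 0.26 and CDKN1A, which encodes p21, by 3.88 ± 0.42 (adjusted p = 0.00054 and 0.0025). Among protein-coding genes named, the largest falls were those of the imprinted gene PEG3 (−5.98 ± 0.35, adjusted p = 0.00051; 31.3 FPKM in wild type) and of CRYZ, a quinone reductase (−5.45 ± 0.15, adjusted p = 5.8e-05; 24.3 FPKM in wild type). PEG3 was under 1 FPKM in every other library too, and CRYZ was under 1 FPKM in all 7 RNF2R libraries.

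Among the lists, 13 of 18 p53 targets rose in the knockout and none fell, also 13 adjusted over the list alone (median 1.39; camera adjusted p = 2.6e-06, adjusted p = 0.2 with an estimated correlation), with BTG2 at 2.46 and AEN at 1.39. Mesoderm and heart genes had 13 of 19 higher (15 adjusted over the list alone; median 1.54; camera adjusted p = 2.5e-06, adjusted p = 0.14 with an estimated correlation), with TBX1 at 3.27 and WT1 at 2.12. Stress and immediate early genes had 13 of 18 higher and 2 lower (15 and 2 adjusted over the list alone; camera adjusted p = 6.6e-06, adjusted p = 0.18 with an estimated correlation), with ASNS at 1.44 and ATF3 at 1.42. Fibroblast genes had 8 of 13 higher and 1 lower (9 and 1 adjusted over the list alone; camera adjusted p = 0.0013, adjusted p = 0.14 with an estimated correlation), with LUM at 4.11 and PDGFRB at −1.29. Trophectoderm and amnion had 4 of 12 higher (5 adjusted over the list alone; camera adjusted p = 0.0012, adjusted p = 0.18 with an estimated correlation), with WNT6 at 2.87. Cell cycle inhibitors had 3 of 6 higher, also 3 adjusted over the list alone (camera adjusted p = 0.011, adjusted p = 0.18 with an estimated correlation). Streak and mesendoderm genes had 4 of 15 higher and 1 lower, 8 and 1 adjusted over the list alone (camera adjusted p = 0.018, adjusted p = 0.51 with an estimated correlation), with MIXL1 at 1.93 and CER1 at 1.20. Mitochondrial transcripts had 6 of 15 higher (9 adjusted over the list alone; camera adjusted p = 0.00039, adjusted p = 0.35 with an estimated correlation), and with equal sums 2 were higher and 1 lower at a camera adjusted p of 0.067.

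Polycomb genes changed singly in the knockout. BMI1, the PCGF4 subunit of canonical PRC1, fell by 3.13 ± 0.32 (adjusted p = 0.0022), AUTS2 fell by 2.52, SUZ12 by 1.03 and EZH2 by 0.76, while CBX7 rose by 1.92 and PCGF1 by 1.34. The lists of PRC1.1 (1 higher and 2 lower of 10), other PRC1 (3 and 3 of 20) and PRC2 subunits (1 and 2 of 11) did not pass (camera adjusted p = 0.79, 0.94 and 0.76). In all, 6772 genes passed, 3735 higher and 3037 lower (55.2% higher). Scaling to equal sums, with sums of 1472910 FPKM in wild type and 2099460 and 2088347 in the knockout, moved the median of all genes by −0.321 log2 and the share higher to 26.4%; the call of PCGF1 ended. The count was 3982 without clone 2, 697 in a fit of these groups alone, and 10944 with the shRNA controls added to wild type. The wild-type library itself differed from the shRNA controls at 5993 genes, 2463 higher and 3530 lower, and KRT8, PCGF1, IFIT1, NES and PLK1, higher against wild type, were within 0.33 log2 of the shRNA controls. EZH2, RYBP and MCM2, lower against wild type, were at −0.25, 0.23 and 0.28 against the shRNA controls (adjusted p = 0.11, 0.076 and 0.061).

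The time courses ask what follows when dox is withdrawn from the RNF2R and BCORR lines. In the RNF2R line HOX genes, mesoderm genes and neural crest genes rose over the 6 days. Of 27 primed pluripotency genes 19 fell, with adjusted p = 0.071 for the list with an estimated correlation. HAPLN1, a link protein of the extracellular matrix (chromosome 5, 83637805 to 83720855), rose from 2.28 FPKM on day 0 to 643 on day 6, a slope of 1.40 ± 0.07 log2 per day (adjusted p = 9.1e-07). HOXB8 (chromosome 17, 48612346 to 48615292) was listed at 0 on day 0 and reached 24.5 FPKM (0.95 ± 0.06 per day, adjusted p = 4.9e-06), and BMP4, a morphogen, rose from 8.86 to 205 FPKM (0.74 ± 0.04, adjusted p = 3.3e-06). The NODAL co-receptor gene TDGF1 fell from 761 to 10.4 FPKM (−0.85 ± 0.16, adjusted p = 0.0031) and DNMT3B from 201 to 27.8 (−0.48 ± 0.04, adjusted p = 1.1e-05).

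Of 38 measured HOX genes, 32 rose in the RNF2R line and none fell (37 adjusted over the list alone; median slope 0.53; camera adjusted p = 1.6e-25, adjusted p = 0.046 with an estimated correlation). Mesoderm and heart genes had 21 of 23 higher, also 21 adjusted over the list alone (median 0.40; camera adjusted p = 4.3e-17, adjusted p = 0.0026 with an estimated correlation), with HAND1 at 0.93 and ISL1 at 0.70. Neural crest and placode genes had 13 of 16 higher (15 adjusted over the list alone; camera adjusted p = 5e-14, adjusted p = 0.011 with an estimated correlation), with TFAP2A at 0.99 and DLX6 at 0.76. Trophectoderm and amnion genes had 9 of 11 higher and 1 lower, the same adjusted over the list alone (camera adjusted p = 2.3e-06, adjusted p = 0.02 with an estimated correlation), with GATA3 at 0.85 and GABRP at −0.44. TGF-beta, BMP and WNT signalling had 14 of 23 higher and 1 lower (16 and 1 adjusted over the list alone; camera adjusted p = 8.2e-09, adjusted p = 0.0056 with an estimated correlation). Blood and endothelium had 6 of 11 higher and 1 lower (camera adjusted p = 0.001, adjusted p = 0.036 with an estimated correlation; TAL1 0.73). Fibroblast genes had 7 of 13 higher (8 adjusted over the list alone; camera adjusted p = 0.00016, adjusted p = 0.046 with an estimated correlation; POSTN 0.70). Cell cycle inhibitors had 3 of 7 higher (5 adjusted over the list alone; camera adjusted p = 0.0056, adjusted p = 0.04 with an estimated correlation), with CDKN2A at 0.66 ± 0.09, from 6.58 to 86.9 FPKM.

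Streak and mesendoderm genes, which rose in shRAB, went both ways in the RNF2R line (1 of 17 higher and 2 lower; camera adjusted p = 0.98, and 3 higher and 2 lower with equal sums). MIXL1 fell there by 0.60 ± 0.14 per day (adjusted p = 0.0081), MESP2 by 0.19 and EVX1 rose by 0.44; without day 6 the calls of MIXL1 (−0.48) and MESP2 (−0.18) ended. Neural ectoderm had 9 of 20 genes higher and 1 lower in the RNF2R line, 10 and 1 adjusted over the list alone (camera adjusted p = 0.001, adjusted p = 0.25 with an estimated correlation), with DLX5 at 1.09. Endoderm had 4 of 17 higher and 1 lower, 7 and 1 adjusted over the list alone (camera adjusted p = 0.014, adjusted p = 0.34 with an estimated correlation, and 0.10 with equal sums), with FOXA1 at 0.61. Primed pluripotency genes fell, 19 of 27 and 20 adjusted over the list alone (median −0.30; camera adjusted p = 2.3e-11, adjusted p = 0.071 with an estimated correlation). Cell cycle genes had 15 of 22 lower (17 adjusted over the list alone; camera adjusted p = 2e-08, adjusted p = 0.13 with an estimated correlation), but 1 higher and 3 lower with equal sums; PCNA was at −0.25. Mitochondrial transcripts had 13 of 15 lower (15 adjusted over the list alone; median −0.17; camera adjusted p = 3.1e-09, adjusted p = 0.12 with an estimated correlation). PRC2 subunits had 6 of 11 lower, also 6 adjusted over the list alone (camera adjusted p = 0.0056, adjusted p = 0.04 with an estimated correlation), but 2 higher and 1 lower with equal sums (camera adjusted p = 0.19). In all, 5992 of 27166 genes had a slope that passed, 2947 higher and 3045 lower (49.2% higher, and 84.5% with equal sums; the sum of FPKM was 1539673 on day 0 and 1058716 on day 6). The count was 3747 without day 0 and 3836 over days 1 to 6 alone in the joint fit.

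In the BCORR line, 14 of 17 endoderm genes and 7 of 17 streak genes rose (adjusted p = 0.052 and 0.38 for the lists with an estimated correlation). SOX17 (chromosome 8, 54457935 to 54460892) rose from 0.870 to 24.8 FPKM (0.77 ± 0.11 log2 per day, adjusted p = 0.0022), GATA6 (chromosome 18, 22169589 to 22202528) from 0.922 to 21.9 (0.70 ± 0.07, adjusted p = 0.00045) and EOMES from 3.74 to 49.5 (0.58 per day). NPPB, which encodes the natriuretic peptide BNP (chromosome 1, 11857464 to 11858945), had the largest slope among protein-coding genes named, 0.97 ± 0.07 (adjusted p = 4.6e-05; 1.74 to 148 FPKM). The skeletal actin gene ACTA1 fell from 279 to 33.2 FPKM (−0.58 ± 0.10, adjusted p = 0.0068), and the collagen gene COL1A1 fell at −0.37 ± 0.03 per day.

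Of 17 endoderm genes, 14 rose in the BCORR line and 1 fell (median 0.52; camera adjusted p = 7.9e-16, adjusted p = 0.052 with an estimated correlation), with HNF4A at 0.52 and APOA1 at 0.81. Streak and mesendoderm genes had 7 of 17 higher, 9 higher and 1 lower adjusted over the list alone (median 0.35; camera adjusted p = 9.6e-05, adjusted p = 0.38 with an estimated correlation), with LHX1 at 0.86 and GSC at 0.60. Trophectoderm and amnion had 4 of 11 higher, 6 and 1 lower adjusted over the list alone (camera adjusted p = 0.011, adjusted p = 0.36 with an estimated correlation). Mesoderm and heart genes had 3 of 23 higher, 6 adjusted over the list alone (camera adjusted p = 0.028, adjusted p = 0.36 with an estimated correlation). Fibroblast genes had 2 of 13 lower, 6 adjusted over the list alone (camera adjusted p = 0.027, adjusted p = 0.36 with an estimated correlation). The p53 targets had 1 of 18 lower, RRM2B at −0.15, and 2 adjusted over the list alone (camera adjusted p = 0.03, adjusted p = 0.62 with an estimated correlation). HOX genes had 0 of 38 higher and 1 lower in limma (0 higher and 2 lower at an unadjusted p under 0.05; camera adjusted p = 0.78), and primed pluripotency 2 of 27 lower, USP44 and LIN28A (camera adjusted p = 0.37). In all, 1750 genes passed, 822 higher and 928 lower (47.0% higher, and 29.3% with equal sums). The count was 655 without day 0, 1084 without day 5, 937 without day 6, 616 over days 1 to 6 alone and 1092 in a fit of this line's libraries alone.

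**Figure D2:**
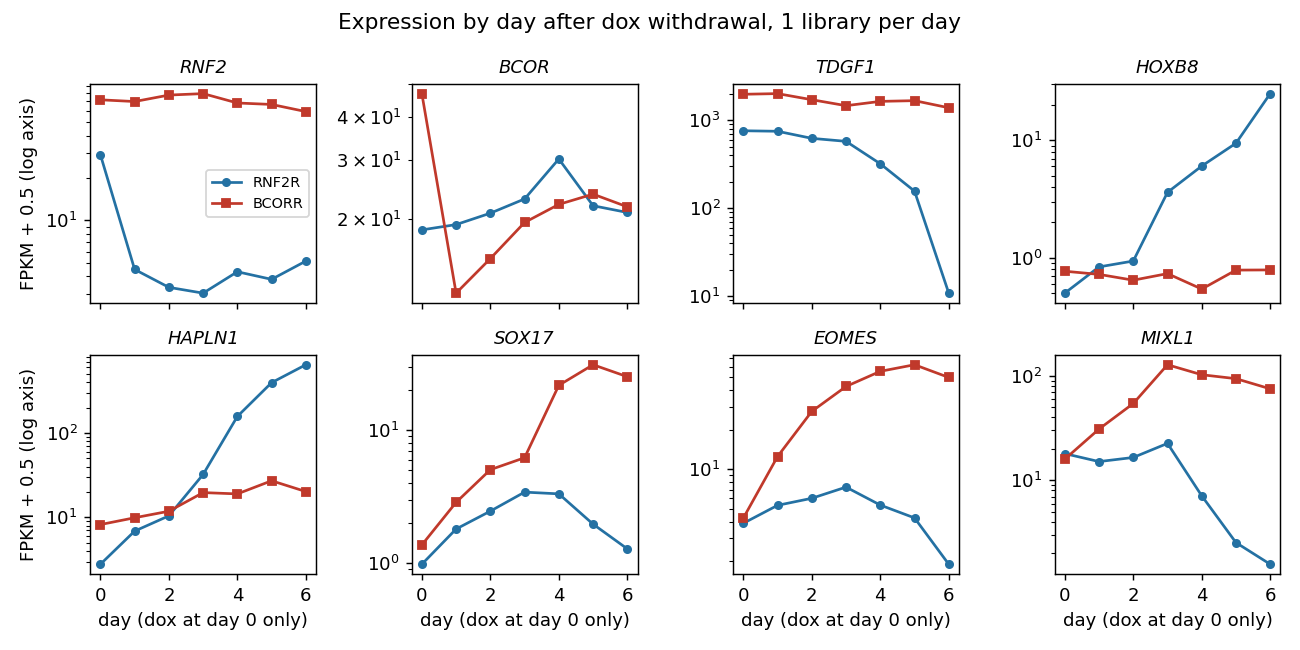
FPKM + 0.5 on a log axis against the day, 1 library per day, in RNF2R and BCORR cells for 8 genes. HOXB8 and HAPLN1 rose in the RNF2R line and SOX17 and EOMES in the BCORR line, while TDGF1 ended at 10.4 FPKM in the RNF2R line.

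**Figure D3:**
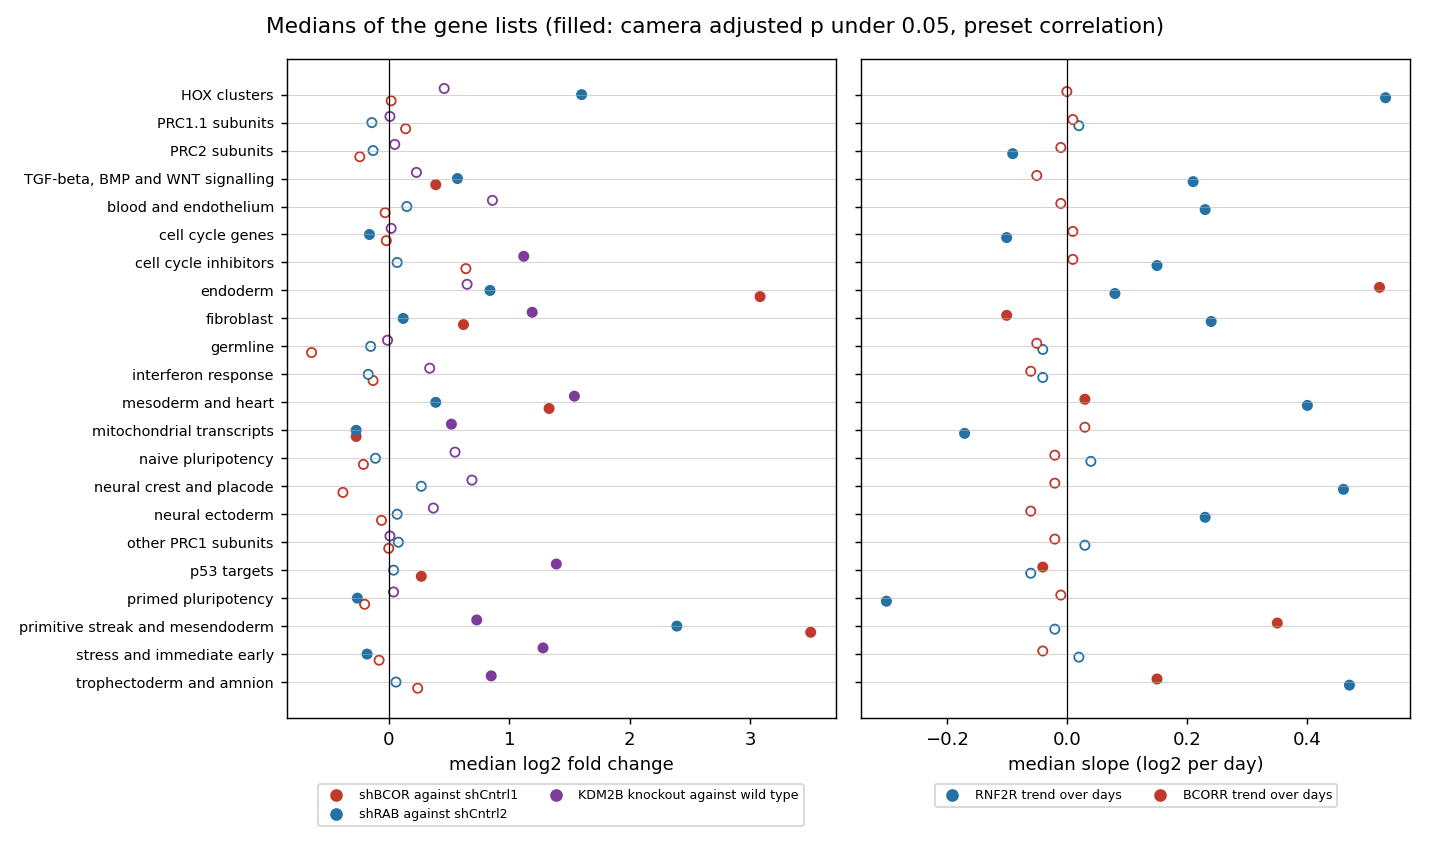
Median log2 fold change of each gene list (left) or median slope in log2 per day (right), 1 point per comparison, filled where the camera adjusted p was under 0.05 with the preset correlation. With an estimated correlation most filled points lost their call, leaving 0 lists in shBCOR, 2 in shRAB, 0 in the knockout, 9 in RNF2R and 0 in BCORR. The median of the measured HOX genes was 1.60 in shRAB and 0.53 per day in the RNF2R line. With equal sums the calls of primed pluripotency and cell cycle genes in shRAB, mitochondrial transcripts in the knockout, and PRC2 subunits and endoderm in the RNF2R line ended.

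BCOR ChIP-seq asks where the protein sits in wild-type cells and what remains without KDM2B or after dox withdrawal in RNF2R cells. In wild type, 23300 peaks covered 23.1 Mb with a median length of 625 bp, and 47.1% (95% interval 46.4 to 47.7) lay within 1 kb of an end of a protein-coding gene. Among the strongest were peaks at SRCIN1 (chromosome 17, 38603132 to 38603340, fold enrichment 62.9) and at RCBTB2 (chromosome 13, 48532478 to 48533243, fold enrichment 55.5). Of the protein-coding genes with the largest changes in the libraries labelled shBCOR, wild-type peaks stood at 7 of 8 that rose and 8 of 8 that fell; in shRAB they stood at 5 of 7 and 3 of 4. The counts were 7 of 9 and 0 of 2 in the knockout, 7 of 7 and 3 of 6 in the RNF2R line, and 6 of 9 and 3 of 9 in the BCORR line. Of all 14917 protein-coding genes tested between groups, 10636 had such a peak. CER1 had a peak at chromosome 9, 14722539 to 14723008, with a fold enrichment of 9.26 in wild type and 5.21 in the knockout, and HOXB8 a broad peak from 48609335 to 48621901 on chromosome 17, with 11.3 in wild type and 3.04 in the knockout. EOMES, MIXL1 and SOX17 had peaks in all 4 lists; COL3A1, CRYZ, PEG3, CST1 and IDO1 had none in any.

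The KDM2B knockout had 15135 peaks over 10.2 Mb, with a median length of 358 bp. Of the wild-type peaks, 46.1% (45.4 to 46.7; 10730 of 23300) overlapped a knockout peak, against 0.878% of shuffled peaks; with overlap of at least 50% of the peak the share was 26.3%, and with stricter peaks in both lists 15.9%. Of the knockout peaks, 78.5% (77.8 to 79.1) overlapped a wild-type peak. Near gene ends the share of wild-type peaks found again was 45.4% (44.4 to 46.3) and elsewhere 46.7% (45.8 to 47.6). All 39 HOX genes, each with a wild-type peak within 1 kb of an end, had a knockout peak there too, as did all 14 endoderm genes and 19 of 22 mesoderm and heart genes with a wild-type peak. HOX genes lie in clusters and can share a broad peak, so these are not 39 separate cases. The number of separate peaks was not counted. Of 13 cell cycle genes with a wild-type peak, 0 had a knockout peak, and of the 11463 protein-coding genes with a wild-type peak 5048 (44%) had one. In RNF2R cells, 37087 peaks with dox and 35815 without were listed. Of the peaks with dox, 76.4% (76.0 to 76.8) overlapped a peak without dox, 96.3% (96.0 to 96.6) near gene ends and 64.7% (64.1 to 65.3) elsewhere. Each condition had 1 ChIP library, so no test between conditions was made, and by the labels the wild-type sample had another antibody than the knockout.

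**Figure D4:**
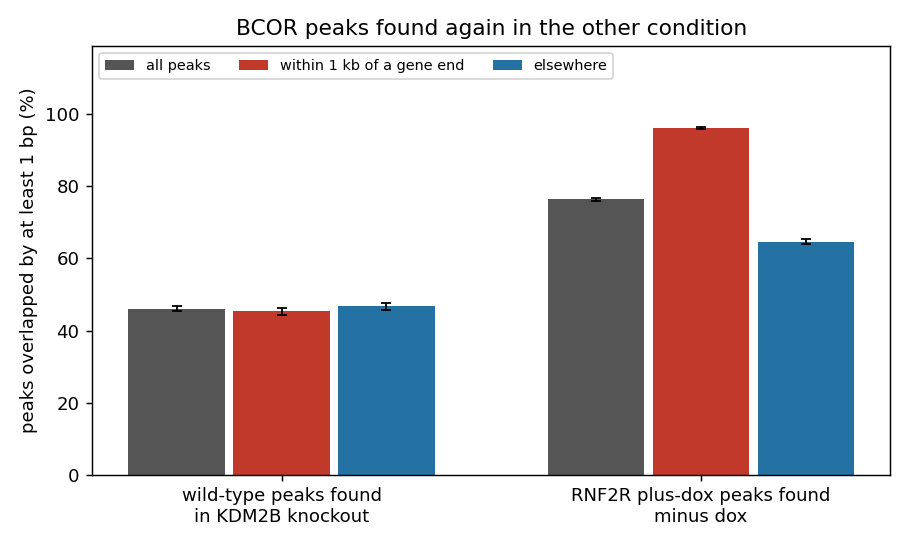
Share of BCOR peaks, in percent, that overlap a peak of the other condition by at least 1 bp, for all peaks, peaks within 1 kb of a protein-coding gene end and peaks elsewhere, with Wilson 95% intervals. In RNF2R cells 96.3% of peaks near gene ends were found again without dox, and in the KDM2B knockout 45.4%.

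Genes with a wild-type BCOR peak numbered 11463 of 19118 protein-coding genes (60%). The share was 39 of 39 for HOX genes, 23 of 24 for neural ectoderm, 22 of 23 for mesoderm and heart and 15 of 16 for neural crest (Fisher's exact adjusted p = 7.5e-08, 0.001, 0.0011 and 0.022). Germline genes had 9 of 22 and naive pluripotency genes 6 of 16 (adjusted p = 0.14 for both). In the RNF2R line, 18.3% of bound genes rose against 8.25% of unbound genes, an odds ratio of 2.49 (95% interval 2.22 to 2.81; Fisher's exact adjusted p = 8.5e-60). The odds ratio of a rise was 1.70 (1.54 to 1.87; adjusted p = 3.1e-29) in the knockout, 1.55 (1.34 to 1.79; adjusted p = 1e-09) in the libraries labelled shBCOR, 1.37 (1.13 to 1.66; adjusted p = 0.0024) in the BCORR line and 1.46 (1.01 to 2.15; adjusted p = 0.062) in shRAB. Of the falls, those in the RNF2R line passed, with fewer among bound genes (0.874, 0.793 to 0.963, Fisher's exact adjusted p = 0.012). That call ended with stronger peaks alone (0.995). In shRAB the odds ratio of a fall, 2.42 (1.01 to 7.03, Fisher's exact adjusted p = 0.062), was above that of a rise, from 36 bound and 6 unbound genes. For falls it was 1.03 in the libraries labelled shBCOR, 0.93 in the knockout and 0.995 in the BCORR line. The balance of higher and lower calls moved with equal sums of FPKM, and these odds ratios were not repeated with that scaling. Fisher's test treats genes as independent, although neighbouring HOX genes can lie within the same broad peak. Camera, which does not, gave p = 0.0077 for bound genes in the RNF2R trend (p = 0.012 with an estimated correlation) and p = 0.13, 0.63, 0.09 and 0.27 in shBCOR, shRAB, the knockout and the BCORR trend.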

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

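The tests of the low BCOR level in shCntrl1, of swapped labels, of the order of the days, of drift and of a step after day 0 alone were chosen only after the result was seen.

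BCOR mRNA in the libraries labelled shBCOR was not called lower than in shCntrl1 (log2 −0.13 ± 0.17, adjusted p = 0.73), although these libraries differed at 2871 genes. A swap of the labels shBCOR and shCntrl1 would put the genes that rose in the BCORR line higher in shCntrl1; the 804 such genes had a median of 0.60 in the opposite direction, against at most 0.04 in 10000 random sets of genes. Against shCntrl2, BCOR was lower in the libraries labelled shBCOR (−0.63 ± 0.17, adjusted p = 0.048), so a low BCOR level in shCntrl1 may account for part of the missing difference. That stays open, since shCntrl1 against shCntrl2 did not pass (−0.50 ± 0.17, adjusted p = 0.13), and BCOR stood as far below shCntrl2 in shRAB, which does not target it (−0.69 ± 0.17, adjusted p = 0.16). Loss of BCOR protein with little loss of mRNA was not tested.

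The KDM2B knockout differed from wild type at 6772 genes, with 1 wild-type library to carry the comparison. Of 6634 of these genes that could be tested, 87.1% had the same sign against both shRNA controls without the wild-type library. With knockout libraries simulated around the shRNA control means and the measured wild-type library kept (20 draws), this share was 61.1% on average and at most 62.1%, although such data still called 5837 genes on average, so a wild-type library that stands apart is not the whole cause. The wild-type library itself differed from the shRNA controls at 5993 genes, but by the labels neither side of the knockout comparison carries an shRNA, so a difference between libraries with and without shRNA bears on that share and not on the 6772 calls. Loss of KDM2B stays open as the biological explanation, and how many calls the single wild-type library adds also stays open.

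Slopes over days passed for 5992 genes in the RNF2R line and 1750 in the BCORR line. Each line is a single series without replicate days, so these calls rest on scatter around a straight line and not on spread between cultures. Among 100 random orders of the days with the real one added, 1 in each line, the real one, gave as many. The highest other counts were 3368 and 956, from orders that correlated with the real days at 0.86 and 0.93. Scatter without any order in the days is thus unlikely to give such counts. A smooth change of 1 culture would also exceed shuffled orders, so drift within a single line stays open. Drift in culture common to both lines is not the whole cause, as slopes correlated at 0.04 across genes and 0.12 across called genes and 230 genes passed in opposite directions, but a shared part stays open, with 258 genes higher in both lines against 89.2 expected and 214 lower against 104.0; a step between days 0 and 1 with no later change would leave days 1 to 6 flat, where 3836 and 616 genes passed. The sign over days 1 to 6 matched in 100% and 100% of called genes, which decides nothing about the step. In a simulation, 0 of 2000 genes with a step alone of 1, 2 or 4 log2 were called by the trend. Selection may thus fix that share. All other simulated genes were flat, so the adjusted threshold was stricter there than in the real data. The loss of RNF2 or BCOR after dox withdrawal stays open, as does a dox effect that differs between the lines, which was not tested.

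The effects of shBCOR and shRAB, each against its own control, differed at 446 genes by a test of the difference, 266 higher and 180 lower in shBCOR. The count was 168 and 204 without shBCOR replicates 1 and 2, 161 and 149 without shRAB replicates 1 and 2, and 252 without shCntrl2 replicate 2. The share higher went from 59.6% to 45.2% without shBCOR replicate 1 and to 48.6% without shCntrl1 replicate 2. The difference was 0.94 ± 0.16 for RNF2 (adjusted p = 0.047), a call that ended under 6 other settings, among them both other scalings (0.96 and 0.96), and without any 1 library but shCntrl1 replicate 2 (between 0.80 and 1.01). It was 4.19 ± 0.33 for SLCO2A1 (adjusted p = 0.0026), 3.53 ± 0.53 for RGCC (0.035), 3.48 ± 0.54 for LGR5 (0.038), −3.76 ± 0.43 for FEZF1 (0.012), −3.22 ± 0.31 for USH1C (0.007) and −3.01 ± 0.47 for PYGM (0.04). The calls of LGR5 and PYGM ended without any 1 of the 8 libraries, that of RGCC without any but shRAB replicate 1 and shCntrl2 replicate 1, and that of FEZF1 without either shBCOR or shRAB library or shCntrl2 replicate 2. Under other settings the call of LGR5 ended 4 times (differences between 3.48 and 4.50), that of RGCC 2 times and that of PYGM 1 time. With a library left out their differences lay between 3.07 and 3.90 for LGR5, 3.07 and 3.60 for RGCC, −3.20 and −2.82 for PYGM, and −3.85 and −3.67 for FEZF1.

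As lists, endoderm genes had a median difference of 2.01 (7 of 16 higher, 12 adjusted over the list alone; camera adjusted p = 1e-13, adjusted p = 0.065 with an estimated correlation). Streak and mesendoderm genes had 1.21 (6 of 15 higher, 8 higher and 1 lower adjusted over the list alone; 8.8e-07 and 0.17). Mesoderm and heart genes had 0.75 (3 of 19 higher, 7 adjusted over the list alone; 1.6e-06 and 0.065). HOX genes had −1.53 (2 of 10 lower, 9 adjusted over the list alone; 1.5e-09 and 0.065). Only HOX genes that passed the filter on FPKM are in this value, and the shRAB libraries alone could admit a gene. PRC1.1 subunits had 0.36 (1 of 10 higher, camera adjusted p = 0.012 and 0.16 with an estimated correlation). This list holds RNF2 and RING1 (0.89 ± 0.26, limma adjusted p = 0.21), the targets of shRAB. The knockdown itself may set part of that shift, and the list was not tested without them. Fibroblast genes had 0.29 (2 of 13 higher; 0.014 and 0.16). The p53 targets had 0.43, with 0 of 18 past the threshold in limma and 8 higher and 1 lower at an unadjusted p under 0.05 (0.0095 and 0.45). These directions were the same under both other scalings.

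The slopes of the BCORR and RNF2R lines differed at 3756 genes, 1830 higher and 1926 lower in BCORR; the count was 2410 without BCORR day 0, 2200 without BCORR day 6 and 1631 over days 1 to 6 alone. With equal sums the share higher went from 48.7% to 10.7%. The slope difference per day was 1.1 ± 0.15 for HES3, 1.04 ± 0.13 for CYP26A1, 1.02 ± 0.21 for CER1, 0.99 ± 0.19 for MIXL1, 0.90 ± 0.15 for PRAC1 and 0.88 ± 0.25 for NANOG (adjusted p between 0.0007 and 0.035). The call of NANOG ended without RNF2R day 1 or 2 and without BCORR day 0, 1, 4, 5 or 6, at differences between 0.80 and 0.92. NANOG went from 116 to 1.76 FPKM in the RNF2R line and from 178 to 377 in the BCORR line, and HES3 from 32.1 to 0.590 and from 33.7 to 93.7. Lower in BCORR were PCDH19 (−1.42 ± 0.27), HAPLN1 (−1.13 ± 0.10), DLX5 (−1.09 ± 0.12), HOXC6 (−1.05 ± 0.16), MCOLN3 (−0.97 ± 0.15), SCUBE1 (−0.97 ± 0.09), IGF2 (−0.95 ± 0.05) and HOXB8 (−0.95 ± 0.09; adjusted p between 1.9e-05 and 0.0055).

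As lists, the median slope difference was −0.55 for HOX genes (29 of 38 lower, 32 adjusted over the list alone; camera adjusted p = 4e-23, adjusted p = 0.087 with an estimated correlation) and −0.44 for neural crest and placode (12 of 16 lower, 14 adjusted over the list alone; 1.4e-13 and 0.014). It was −0.33 for mesoderm and heart (16 of 23 lower, 17 adjusted over the list alone; 8.6e-12 and 0.012), −0.33 for trophectoderm and amnion (7 of 11 lower and 1 higher; 0.001 and 0.087) and −0.31 for fibroblast genes (6 of 13 lower; 2.4e-06 and 0.033). It was −0.27 for blood and endothelium (3 of 11 lower and 1 higher; 0.011 and 0.09), −0.24 for neural ectoderm (9 of 20 lower and 1 higher; 1.5e-05 and 0.13) and −0.24 for TGF-beta, BMP and WNT signalling (10 of 23 lower; 2.2e-06 and 0.014). It was 0.38 for primed pluripotency (11 of 27 higher, 21 adjusted over the list alone; 2.1e-08 and 0.13), 0.32 for endoderm (8 of 17 higher; 8.2e-05 and 0.13) and 0.22 for streak and mesendoderm (5 of 17 higher; 0.0075 and 0.42). Mitochondrial transcripts had 0.18 (11 of 15 higher; 6.8e-09 and 0.13), and 4 higher with equal sums. Cell cycle genes had 0.11 (11 of 22 higher; 2e-07 and 0.14), and 1 higher and 1 lower with equal sums. With equal sums primed pluripotency had 5 higher and 1 lower, and streak and mesendoderm 4 and 1.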

How the results depend on the processing

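The fit on protein-coding genes alone and the gene body as the bound region were chosen only after the result was seen. Other settings gave 7332 values of 460 single-gene results. Of these values, 6402 kept their direction and, except for the rank trend, their side of the threshold. Another 890 lost their call, 8 gained one and 32 changed sign. The rank trend was judged on direction alone, and a gene filtered out under a setting has no value there. Of 223 values of 35 results over many genes or peaks, 166 stayed within the bounds set, and the others are given here. The number of reads is not in the table, so what depth limits could not be worked out; false calls among genes left unchanged in the simulation numbered between 0 and 6. The replicate block has no value for the knockout, whose control has 1 library. Where a setting leaves a group with 1 library, that library is assumed to vary like the others. Except where samples or genes are fewer by construction, the cause was not tested.

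With equal sums of FPKM the control comparison had 1007 genes in place of 1705. RNF2 in shBCOR went to 0.10, BCOR in shBCOR to 0.002, RING1 in the knockout to −0.19 and RING1 in the BCORR slope minus the RNF2R slope to −0.10. In fits of only the groups compared, with fewer samples, counts were 1358 for shBCOR, 256 for shRAB, 697 for the knockout and 250 for the control comparison, and a fit of only the BCORR libraries had 1092. With the replicate block they were 1872 for shBCOR, 244 for shRAB, 192 for the control comparison and 180 for the shBCOR effect minus the shRAB effect.

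With fewer samples, leaving out 1 library gave between 1150 and 2201 genes for shBCOR (1150 and 1155 without shBCOR replicates 1 and 2) and between 174 and 316 for shRAB (177 and 174 without shRAB replicates 1 and 2). The control comparison had between 363 (without shCntrl1 replicate 2) and 2257 (without shCntrl1 replicate 1, 60.7% higher in place of 39.9%), with 413 without shCntrl2 replicate 2. The difference of effects had between 149 and 325: 168 and 204 without shBCOR replicates 1 and 2, 161 and 149 without shRAB replicates 1 and 2, and 252 without shCntrl2 replicate 2. The knockout had 4608 without clone 1 and 3982 without clone 2. The RNF2R trend had between 3747 (without day 0) and 6193, and the BCORR trend between 655 (without day 0) and 1661, with 1084 without day 5 and 937 without day 6. The difference of slopes had between 2200 (without BCORR day 6) and 3937, with 2410 without BCORR day 0. Over days 1 to 6 only, the counts were 3836 for RNF2R, 616 for BCORR and 1631 for their difference.

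With shCntrl2 as control, shBCOR had 5631 genes, with RNF2 at 0.60 (adjusted p = 0.014), and with the mean of both controls 4558, with RNF2 at 0.29. The count of shRAB was 4039 with shCntrl1 as control and 1645 with the mean of both, and the pseudogene PSMC1P1 went to −1.76 with shCntrl1. The knockout had 10944 with both shRNA controls added to wild type.

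Other changes of sign were in target genes that did not pass. With 1 library left out, shBCOR had BCOR between −0.40 and 0.15 (without shBCOR replicate 2) and RNF2 between −0.16 and 0.11 (without shCntrl1 replicate 2). KDM2B in shRAB lay between −0.41 and 0.14 (without shCntrl2 replicate 1). In the control comparison KDM2B lay between −0.46 and 0.095 and RING1 between −0.14 and 0.30, with 0.095 and −0.14 without shCntrl2 replicate 2 and RING1 at −0.004 without shCntrl1 replicate 2. KDM2B in the difference of effects lay between −0.48 and 0.069 (without shCntrl2 replicate 2). In the RNF2R trend, RNF2 lay between −0.43 and 0.059 (without day 0), and KDM2B between −0.015 (without day 0) and 0.10, with −0.001 without day 5. In the difference of slopes, RNF2 lay between −0.10 (without RNF2R day 0) and 0.39, and BCOR between −0.17 and 0.13 (without BCORR day 0). RING1 lay there between −0.035 (without RNF2R day 0) and 0.021, with −0.002 without RNF2R day 6, −0.002 without BCORR day 2 and −0.021 without BCORR day 6. BCOR in the BCORR trend lay between −0.12 and 0.18 (without day 0). Over days 1 to 6 only, KDM2B and RNF2 in RNF2R were at −0.015 and 0.059, BCOR in BCORR at 0.18, and the differences at −0.12 for RNF2, 0.14 for BCOR and −0.036 for RING1. With a rank trend the Spearman value was 0.14 for BCOR in BCORR, and the difference for RNF2 was −0.50.

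With an estimated correlation 0 lists passed by camera in shBCOR, 2 in shRAB, 0 in the knockout, 9 in RNF2R and 0 in BCORR, in place of 7, 10, 8, 14 and 6. Among only genes past the threshold, Spearman correlations were 0.662 for shBCOR with shRAB, 0.543 for shBCOR with BCORR, 0.271 for shRAB with RNF2R and 0.551 for shRAB with BCORR. Of the wild-type peaks, 26.3% were found again in the knockout with 50% overlap, 15.9% with −log10 q of at least 5 in both lists and 46.9% in the upper part of fold enrichment. For RNF2R cells with and without dox these shares were 65.3%, 51.1% and 77.5%. For bound genes, the odds ratio of a fall in the knockout was 0.817 within 5 kb and 0.861 with the gene body, which passed. The odds ratio of a rise in shRAB was 1.93 within 0 kb, 1.99 with stronger peaks and 1.64 with the gene body, which passed. That of a fall in RNF2R was 0.995 with stronger peaks and no longer passed.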

Other observations

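The hypoxia list and the test of whether genes that lose the BCOR peak rise were chosen only after the result was seen.

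Some genes of the response to low oxygen differed between shCntrl2 and shCntrl1. BNIP3 was lower in shCntrl2, with a log2 difference of −2.19 ± 0.15 (adjusted p = 0.0017), as were ANKRD37 (−1.78 ± 0.22, adjusted p = 0.014), EGLN1 (−1.83 ± 0.18, adjusted p = 0.006) and HK2 (−1.01 ± 0.17, adjusted p = 0.027). With equal sums HK2 no longer passed (−0.95, adjusted p = 0.092), and the others did. Of 21 listed hypoxia genes, 11 were lower and 0 higher in limma (median −0.90), and with equal sums 9 were lower and 0 higher (median −0.83). The list was made because such genes had been seen to differ here, so no test of it stands in this comparison, where camera gave p = 0.053 with an estimated correlation. In the knockout 7 were higher and 1 lower (camera p = 0.031, p = 0.37 with an estimated correlation). In shBCOR 2 were higher and 4 lower, in the RNF2R line 2 and 3, and in the BCORR line 1 and 4. By camera these lists did not pass. The 4 lower in shBCOR were ANKRD37 (−1.58), BNIP3L (−0.95), HK2 (−0.85) and KDM3A (−0.50). All 4 were also lower in shCntrl2 against shCntrl1, so these falls cannot be told apart from a difference of shCntrl1. MXI1 and PDK1 rose in shBCOR (1.02 and 1.67) and stood at −0.45 and −2.01 in shCntrl2 against shCntrl1.

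BCOR sat at all 10 genes of PRC1.1 subunits in wild type (Fisher's exact adjusted p = 0.027 against all protein-coding genes) and at 18 of 20 genes of other PRC1 subunits (adjusted p = 0.022). It also sat at 16 of 18 p53 targets, 16 of 18 stress and immediate early genes (adjusted p = 0.029 for both) and 20 of 26 primed pluripotency genes (adjusted p = 0.17). Of these bound genes, 7, 14, 7, 7 and 14 had a knockout peak within 1 kb of an end. All 22 cell cycle genes had a peak in RNF2R cells with dox and without, against 13 in wild type. Over all protein-coding genes the share was 75% and 74.6%, against 60% in wild type, and the labels give another antibody and fixation for RNF2R cells.

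Of wild-type peaks near the ends of genes on the developmental lists, 159 of 169 (94.1%) were found again in the knockout, against 44.6% of peaks near other genes (odds ratio 19.8, 95% interval 10.4 to 42). A candidate explanation is that wild-type peaks there are longer. Within the longest 25% of the peaks, 97.9% against 75.9% were found again, an odds ratio of 14.9 (4.97 to 73.3). These peaks ran from 1206 to 25770 bp and held 144 of the 169 developmental peaks, so length still varied among them. In the next 25%, from 625 to 1206 bp, 11 of 12 against 37.5% were found again (18.3, 2.66 to 789). In the shortest 25% the interval was wide (0.347 to 22.8). How much of the difference length accounts for stays open. The antibody differs between these conditions by the labels, so its part could not be told apart from the loss of KDM2B.

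The hypothesis that genes that lose the BCOR peak rise in the knockout was tested among bound genes. Of 5896 genes without a knockout peak, 22% were called higher, and of 4740 with such a peak 26% were. The odds ratio was 0.803 (0.733 to 0.879; Fisher's exact p = 1.7e-06). In comparisons without the knockout the odds ratio was lower still, 0.354 in shBCOR, 0.251 in shRAB, 0.323 in the RNF2R line and 0.421 in the BCORR line. Genes without a knockout peak thus rose less often in each of these 5 comparisons, a value below 1 in the knockout excludes nothing, and the hypothesis stays open.

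Rises in the knockout and in the RNF2R line were common to 804 genes, against 379 expected by chance, and falls to 382 against 358, while 722 genes went opposite ways (Spearman 0.06). Rises in both time courses were common to 258 genes against 89.2 expected and falls to 214 against 104.0, with 230 opposite (Spearman 0.04). Both slopes come from the same fit and share the same spread per gene, so their calls are not independent. Expected numbers of opposite calls were not worked out, so the counts of opposite calls cannot be set against chance here. Rises in the libraries labelled shBCOR and the RNF2R line were common to 511 genes against 167, with 220 opposite and a Spearman correlation of 0.17 over all genes. Small RNA genes made up 92 of the calls in shBCOR, 50 in shRAB, 176 in the knockout, 107 in the RNF2R line and 17 in the BCORR line.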
